A study of Homo sapiens with 5 samples.

How the data were processed

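The series measured mature miRNAs in Caco2 cells, a human colorectal adenocarcinoma line that forms polarised epithelial sheets, carrying either a non-target shRNA (NT) or an shRNA against PLEKHA7, a protein of the adherens junction. RNA was read on the NanoString nCounter Human v2 miRNA panel, in which reporter barcodes bound to each target are counted without amplification. Of 5 samples, 2 were NT (replicates 1 and 3) and 3 were shPLEKHA7 (replicates 1, 2 and 3). Groups came from the sample titles, and the source field of 2 of the 3 shPLEKHA7 samples carried another PLEKHA gene number, which was not followed. No NT replicate 2 was among the samples. The panel carries no probe for PLEKHA7, so its knockdown was not analysed here.

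The authors deposited a raw table of whole-number counts per probe and lane, with 734 miRNA probes (654 human, 80 viral), 8 negative-control probes, 6 positive-control spike-in probes and 5 mRNA probes. It held 0 values of 0, and 12 probes stood at 1 in all 5 lanes. The software that exported it was not stated. A second deposited table held normalized signal values for the same lanes. Although that table is named for positive controls, 100% of its human miRNA and mRNA values lay within 0.02 of the raw count times 1 factor per lane, and those factors equalised the geometric mean of the 5 housekeeping mRNAs at 1802.2. Spike-in totals after that scaling still had a coefficient of variation of 12.37%. Viral probe values in the deposited normalized signal equalled the raw count in 100% of cases, so viral probes had been left unscaled. A baseline column equalled the mean of the NT lanes, and the signed fold columns built on it were not used here.

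The fixed test was the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the raw counts of the miRNA probes with TMM scaling, group as the only term and a Benjamini-Hochberg adjusted p under 0.05. A probe was tested if it exceeded the mean plus 2 SD of that lane's negative controls in at least 2 samples, which kept 204 of 734. Control and mRNA probes were left out of library sizes and tests. miRNA lists fixed before the data were examined were tested with camera (limma 3.58.1, preset correlation 0.01) where at least 3 members were tested, then with an estimated correlation and with fry. Single values were compared with 2-sided exact permutation tests over the 10 splits of 2 against 3 samples, whose smallest p is 0.1. The global shift was the median log2 fold change under the deposited scaling, which had been planned as a positive-control scaling and turned out to be a housekeeping one. Total spike-in counts were therefore added as a scaling after the data had been seen, as was a fit of human probes alone.

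Named miRNAs followed a rule fixed beforehand. It took the 10 largest rises and 10 largest falls among called probes whose groups did not overlap, the 5 most abundant probes, up to 4 abundant members of each list, and all tested members of the miR-30, let-7/miR-98 and miR-200 families. Values are TMM-normalized counts as mean ± SD, and fold changes are log2 with an SE. For edgeR that SE was derived from the test, as the absolute log2 fold change over the square root of its F statistic. For limma it is the SE of the fit. Alternatives covered other scalings, DESeq2 1.42.0, limma on the deposited values with a pseudocount of 1, background subtraction with a floor of 1, other filters, a block on replicate number, an adjusted p under 0.1 and leaving out each sample.

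Total miRNA counts ran from 32138 to 58298 per lane, and the limit of detection ran from 11 to 24.45 counts. On simulated data of 204 probes with these group sizes, edgeR called 75.3% of 2-fold changes, 33.4% of 1.5-fold changes and 0.8% of unchanged probes. Every simulated probe had the same dispersion (0.0153), which real probes need not share, so these shares hold for that setting only. Replicate numbers shared between the groups were not taken as pairs, because the labels do not say that a number marks 1 infection set. The deposited column names of same-numbered samples do carry codes that end alike, without saying what they mean. As no build is named in the deposited tables, the RefSeq gene table of assembly GRCh38.p14 served only to find which miRNA genes neighbour each other, and no coordinates are given.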

Results

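MicroRNAs were counted in Caco2 cells with a non-target shRNA (NT, n = 2) or an shRNA against the junction protein PLEKHA7 (shPLEKHA7, n = 3), to ask how PLEKHA7 depletion affects miRNA levels. Total miRNA counts were 34942 and 50372 in NT replicates 1 and 3, and 47975, 32138 and 58298 in shPLEKHA7 replicates 1, 2 and 3. Each lane's own 5 most abundant probes took 34.6% to 36.85% of its miRNA count. By mean normalized count over all lanes the top 5 were miR-92a, miR-720, miR-373, miR-21 and the joint probe for miR-20a and miR-20b, which were not the top 5 of every lane.

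The largest change in absolute counts was in miR-21, a miRNA abundant in colorectal cancer, which fell from 3349 ± 992 normalized counts in NT to 1531 ± 241 in shPLEKHA7 cells (log2 fold change -1.13, SE 0.20, adjusted p = 0.0199). miR-24, miR-23a and miR-23b, which are transcribed in the miR-23-27-24 clusters, fell with it. miR-30a, miR-29a, let-7g and miR-574-5p were also lower. In the other direction miR-503, miR-215, miR-19a, miR-302d and miR-302a were higher in shPLEKHA7 cells. In all, 5 of 204 tested probes were higher and 8 lower, and in all 13 the groups did not overlap. The numbers ending the deposited column names, read as lane positions, put both NT samples ahead of all shPLEKHA7 samples, so lane position and group cannot be told apart in any comparison here.

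miR-503 (TAGCAGCGGGAACAGTTCTGCAG), a relative of miR-16, rose from 4.1 ± 0.6 to 24.6 ± 7.2 normalized counts (log2 fold change 2.50, SE 0.48, adjusted p = 0.0211). Its raw counts were 3 and 5 in the NT lanes, both below the limit of detection. The same held for miR-215 (11 and 17) and miR-302d (10 and 18), so these 3 folds are set against NT levels not above background, and neither their sizes nor their order are measured. miR-215 (ATGACCTATGAATTGACAGAC), an miRNA of the intestinal epithelium, rose from 14.6 ± 1.4 to 33.8 ± 9.1 (log2 1.22, SE 0.31, adjusted p = 0.048). miR-19a, a member of the miR-17-92 cluster, rose from 26.1 ± 7.2 to 58.6 ± 8.7 (log2 1.15, SE 0.24, adjusted p = 0.0283). miR-302d and miR-302a, known from pluripotent stem cells, rose by log2 1.13 (SE 0.25) and 0.92 (SE 0.22), with adjusted p of 0.0317 and 0.0399. Of the 5 rises, 2 were above background in all 5 samples (miR-19a and miR-302a), against 7 of the 8 falls.

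Among the falls, miR-24 (TGGCTCAGTTCAGCAGGAACAG) went from 316 ± 9.0 to 174 ± 12.2 normalized counts (log2 -0.85, SE 0.13, adjusted p = 0.0186). miR-23a went from 251 ± 18.9 to 149 ± 9.7 (log2 -0.77, SE 0.14) and miR-23b from 196 ± 56.8 to 113 ± 7.4 (log2 -0.79, SE 0.19). miR-30a (TGTAAACATCCTCGACTGGAAG) went from 179 ± 7.1 to 99.8 ± 15.8 (log2 -0.86, SE 0.16, adjusted p = 0.0211). miR-29a, let-7g and miR-574-5p had log2 fold changes of -0.67, -0.65 and -1.13, with adjusted p of 0.0317, 0.0269 and 0.0317. miR-574-5p was above the limit of detection in 1 of the 3 shPLEKHA7 lanes (raw counts of 20, 12 and 17).

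The calls rested on both NT libraries. Without NT replicate 1 edgeR called 0 higher and 1 lower (38 probes with an unadjusted p under 0.05), and without NT replicate 3 it called 0 and 0 (34 such probes), each time with a lone NT sample assumed to vary like the shPLEKHA7 samples. Without shPLEKHA7 replicate 1 the counts were 9 higher and 9 lower. The numbers called also moved with the scaling: the deposited scaling gave 4 higher and 2 lower, total counts 12 and 8, and spike-in scaling, chosen after seeing the data, 4 and 29. Under the deposited scaling the called falls were all slightly larger than under TMM (miR-24 at log2 -0.915, let-7g at -0.703). The called rises were all slightly smaller (miR-302a at 0.84). The common dispersion was 0.0408 there against 0.0153 under TMM, so its fewer lower calls do not mean smaller falls. Other tests gave 7 and 23 (limma on median-centred deposited values, which changes scaling and test together) and 2 and 9 (DESeq2). Leaving out a sample moved the log2 fold change of 2 of the 13 by over 1.5 times, that of miR-21 from -1.13 to -0.75 without NT replicate 3 and that of miR-23b from -0.79 to -0.48 without NT replicate 1. With all samples kept, 6 others moved as much: miR-302a (to 0.57), let-7g (-0.99) and miR-29a (-1.01) under spike-in scaling, and miR-302d (1.86), miR-503 (3.96) and miR-574-5p (-1.73) after background subtraction. All 13 kept their direction wherever they were tested, which their non-overlapping groups in the same 5 lanes made likely beforehand. Of 204 tested probes 98 (48%) had groups that did not overlap, where exchangeable lanes would give 20% for a single probe. Probes share their lanes and are not independent trials, and this share was not computed for other splits, so it is no test against chance.

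**Figure D1:**
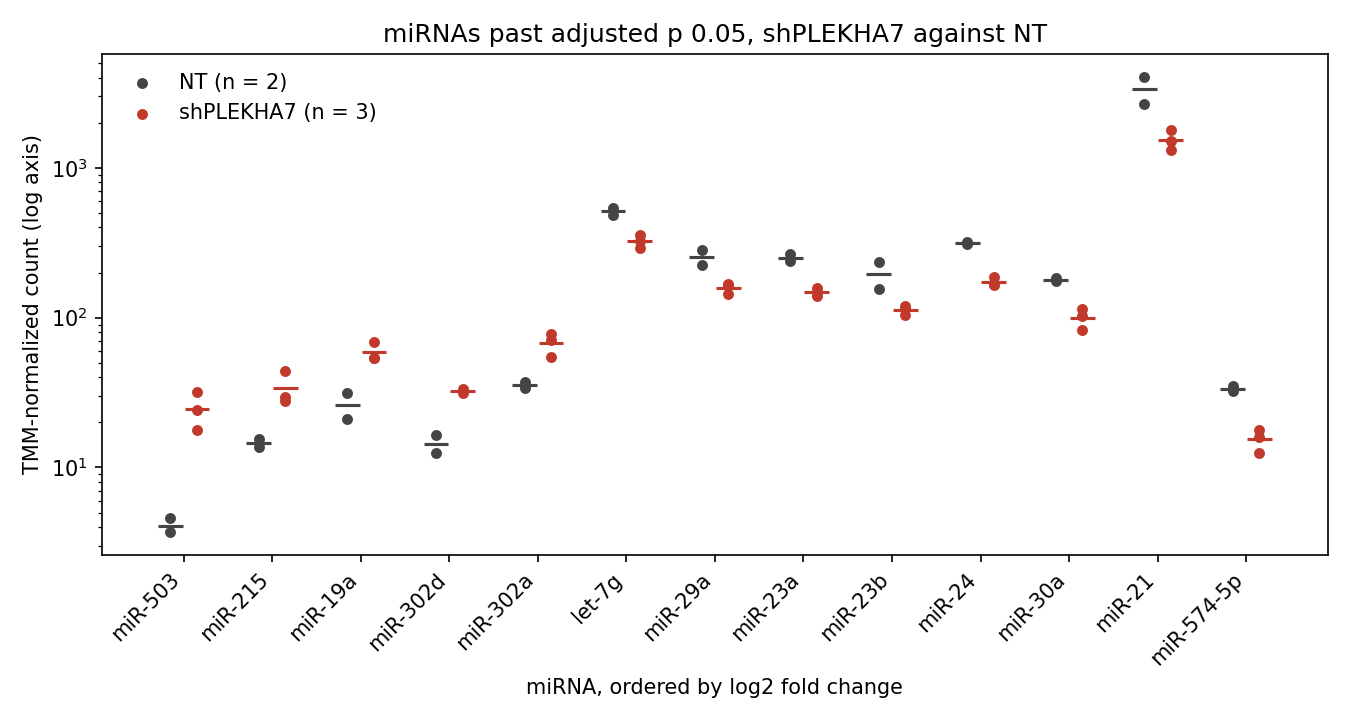
TMM-normalized counts (log axis) of the 13 called miRNAs in each sample, with NT (n = 2) in grey, shPLEKHA7 (n = 3) in red and horizontal bars at group means. The groups do not overlap for any of the 13, and miR-503 has the lowest counts, with a mean of 4.1 in NT.

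Lists fixed beforehand showed the miR-23-27-24 clusters lower, with 3 of 4 tested members down and the fourth, miR-27a, at log2 -0.13 (SE 0.36). Their camera adjusted p was 0.000475, against an adjusted p of 0.323 with an estimated correlation and 0.0124 by fry. The colorectal oncomiRs were all at or below 0, with a median of log2 -0.56 (camera adjusted p = 0.00402, adjusted p = 0.409 with an estimated correlation, adjusted p = 0.064 by fry). Without NT replicate 3, where 5 members were tested, their median was -0.23 and the camera adjusted p 0.102. Of their 6 tested members only miR-21 passed over all probes, and 4 were lower adjusted over the list alone. miR-183 and miR-96, which are transcribed together, stood at log2 -0.59 (SE 0.16, adjusted p = 0.0606) and -0.52 (SE 0.19, adjusted p = 0.12). Leaving the replicate block aside, 4 of 13 other settings that kept all samples called miR-183 and 2 called miR-96. The block called miR-183 (adjusted p = 0.0206) but not miR-96 (0.0616). With a sample left out miR-183 ran from -0.68 to -0.48 and miR-96 from -0.72 to -0.23. Under the scaling to the top 100 probes and to total counts 1 of the 6 turned positive. With an estimated correlation 0 of the 14 lists tested passed, and by fry 1 did, the miR-23-27-24 clusters.

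In the miR-30 family 1 of 5 tested members fell (miR-30a), and 3 were lower adjusted over the list alone, with a camera adjusted p of 0.0273 (adjusted p = 0.409 with an estimated correlation, adjusted p = 0.064 by fry). That call was lost without NT replicate 3 (adjusted p = 0.104), shPLEKHA7 replicate 1 (0.123) or shPLEKHA7 replicate 3 (0.0577), under the deposited (0.0834) and spike-in (0.0699) scalings, and among probes above background in all samples (0.0589). The median of the family, log2 -0.40, ran from -0.49 to -0.33 with a sample left out. miR-30d, miR-30b and miR-30e were at log2 -0.48 (SE 0.14), -0.40 (SE 0.14) and -0.35 (SE 0.22), and miR-30c was at 0.24 (SE 0.20), which turned to -0.09 under spike-in scaling. With the replicate block set aside, 3 of 13 other settings that kept all samples called miR-30b (highest adjusted p 0.545, under the deposited scaling) and 2 called miR-30d (highest 0.372, likewise). The block called miR-30b (adjusted p = 0.00396) but not miR-30d (0.087). Neither was called with a sample left out, where miR-30b ran from -0.49 to -0.26 and miR-30d from -0.57 to -0.33. In the let-7/miR-98 family let-7g fell, and let-7d, let-7b and let-7i were at log2 -0.71 (SE 0.21), -0.59 (SE 0.27) and -0.55 (SE 0.16), while let-7a and let-7f were at 0.004 (SE 0.14) and 0.008 (SE 0.14), let-7c at 0.18 (SE 0.28) and miR-98 at 0.14 (SE 0.27). The camera adjusted p of that family was 0.0626, and 1 of its 8 members was called over all probes, 3 adjusted over the list alone. Without NT replicate 3 the list passed (adjusted p = 0.0272, adjusted p = 0.409 with an estimated correlation over all samples), and without NT replicate 1 its median went from log2 -0.27 to -0.06 (adjusted p = 0.289). let-7d was called in 6 of 13 other settings that kept all samples, the replicate block aside, and in 2 of 5 with a sample left out. The block called it too (adjusted p = 0.0471). Its log2 fold change was -0.36 without NT replicate 1 and -0.97 without NT replicate 3, and that of let-7b was -0.15 and -0.94. let-7a and let-7f turned negative under the deposited, DESeq2 and spike-in scalings, and let-7c and miR-98 under spike-in scaling.

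The miR-17-92 and paralog clusters, which promote proliferation, had all 10 tested members above 0 with a median of log2 0.25, though only miR-19a was called (camera adjusted p = 0.0451, adjusted p = 0.409 with an estimated correlation, adjusted p = 0.0613 by fry). That call was lost without NT replicate 3 (adjusted p = 0.104), shPLEKHA7 replicate 1 (0.123, with a median of 0.16) or shPLEKHA7 replicate 3 (0.103), and under the deposited (0.153) and spike-in (0.284) scalings. Under spike-in scaling 3 of the 10 stayed positive and the median was -0.09. miR-92a, miR-19b and miR-25 stood at log2 0.20 (SE 0.16), 0.37 (SE 0.15) and 0.11 (SE 0.13), and the joint miR-20a and miR-20b probe at 0.26 (SE 0.13). Apart from the replicate block, 2 of 13 other settings that kept all samples called miR-19b and 1 the joint probe. The block called miR-19b (adjusted p = 0.0461) but not the joint probe (0.0929). Neither was called with a sample left out, where miR-19b ran from 0.18 to 0.63. In the pluripotency list, miR-302a and miR-302d were higher, while the abundant miR-373, miR-372 and miR-371-3p were at log2 -0.19 (SE 0.12), -0.31 (SE 0.15) and -0.07 (SE 0.12), and miR-371-5p at 0.12 (SE 0.16). With a sample left out miR-372 ran from -0.45 to -0.11. Over the 8 members of the list the camera adjusted p was 0.293, with 2 called over all probes and 3 adjusted over the list alone. Its median of log2 0.27 was 0.05 without NT replicate 1 and 0.59 without NT replicate 3.

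Members of the miR-200 family, which mark epithelial identity, were not called (0 of 5, also 0 adjusted over the list alone, camera adjusted p = 0.293). Of 12 other settings that kept all samples, the replicate block aside, 1 called miR-200a, spike-in scaling (adjusted p = 0.0473). The block did not (0.389). miR-200c was at 997 ± 0.2 normalized counts in NT and 897 ± 34.5 in shPLEKHA7 cells (log2 -0.15, SE 0.12). miR-200a, miR-200b and miR-429 were at log2 -0.39 (SE 0.18), -0.31 (SE 0.15) and -0.14 (SE 0.23), and miR-141 was at 0.14 (SE 0.25), turning to -0.17 under spike-in scaling. In the intestinal list only miR-215 of 3 was called, and miR-192 and miR-194 were at log2 -0.01 (SE 0.19) and 0.16 (SE 0.16), with a camera adjusted p of 0.329 for the list. miR-194 turned to -0.16 under spike-in scaling, and miR-192 turned positive under total-count and top-100-probe scaling. In the Drosha-independent list, whose members bypass or only partly need the Microprocessor, miR-320a, miR-484 and miR-1226 were at log2 1.66 (SE 0.50), 0.46 (SE 0.17) and 0.42 (SE 0.53). None was called over all probes, 2 were higher adjusted over the list alone, and the camera adjusted p was 0.0901. miR-320a and miR-1226 had NT raw counts of 2 and 11, and of 9 and 13, all below the lanes' limits, so their folds are against a group not above background. miR-320a was called in 6 of 11 other settings that kept all samples, the replicate block aside. Those count the equal deposited and housekeeping scalings separately. The block called miR-320a too (adjusted p = 0.0251). It was also called in 1 of 5 fits with a sample left out, where it ran from 1.09 to 3.11.

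Other lists passed no threshold. Of 39 C19MC cluster probes on the panel only 8 were tested. All 8 were above 0 at a median of log2 0.27 (camera adjusted p = 0.156), with miR-1283 at 0.22 (SE 0.24) and miR-512-5p at 0.20 (SE 0.21). Under DESeq2, deposited and spike-in scaling 7, 6 and 3 of the 8 were above 0. The filter on 2 samples is more easily met by 3 shPLEKHA7 than by 2 NT samples, which can favour members that rose. The 4 above background in all samples had a median of 0.19 (camera adjusted p = 0.529). Without shPLEKHA7 replicate 2 only 4 of the 8 were tested, at a median of 0.06 (adjusted p = 0.832). The 14q32 cluster, with 7 of 47 probes on the panel tested, had a camera adjusted p of 0.538. Its miR-379 was at log2 1.02 (SE 0.37, adjusted p = 0.12) against NT raw counts of 9 and 17, below both limits. The miR-15/16 family had an adjusted p of 0.538, with miR-15b at log2 -0.33 (SE 0.12), miR-16 at -0.06 (SE 0.14) and miR-15a at 0.0 (SE 0.14). Markers of blood cells (adjusted p = 0.834) and of stroma (adjusted p = 0.871) did not pass, with miR-223 at log2 0.30 (SE 0.25), miR-126 at -0.52 (SE 0.30) and miR-214 at 0.84 (SE 0.34). With a sample left out miR-126 ran from -0.89 to -0.36 and miR-214 from 0.48 to 1.08, and 1 of these 5 fits called miR-214. The stroma list had a median of -0.07 and a mean of 0.04, and the blood list a median of 0.08 and a mean of -0.11. Without NT replicate 1 these medians were 0.16 and 0.37, and without NT replicate 3 they were -0.26 and -0.17. Lists with fewer than 3 tested members had no list test. Among them miR-29c was at log2 -0.07 (SE 0.22), miR-34a at -0.13 (SE 0.22), miR-221 at -0.23 (SE 0.13), miR-222 at -0.06 (SE 0.27), miR-205 at -0.46 (SE 0.17), miR-203 at -0.17 (SE 0.21), miR-9 at -0.58 (SE 0.26), miR-128 at -0.29 (SE 0.26), miR-206 at 0.16 (SE 0.27) and miR-208a at -0.06 (SE 0.37).

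**Figure D2:**
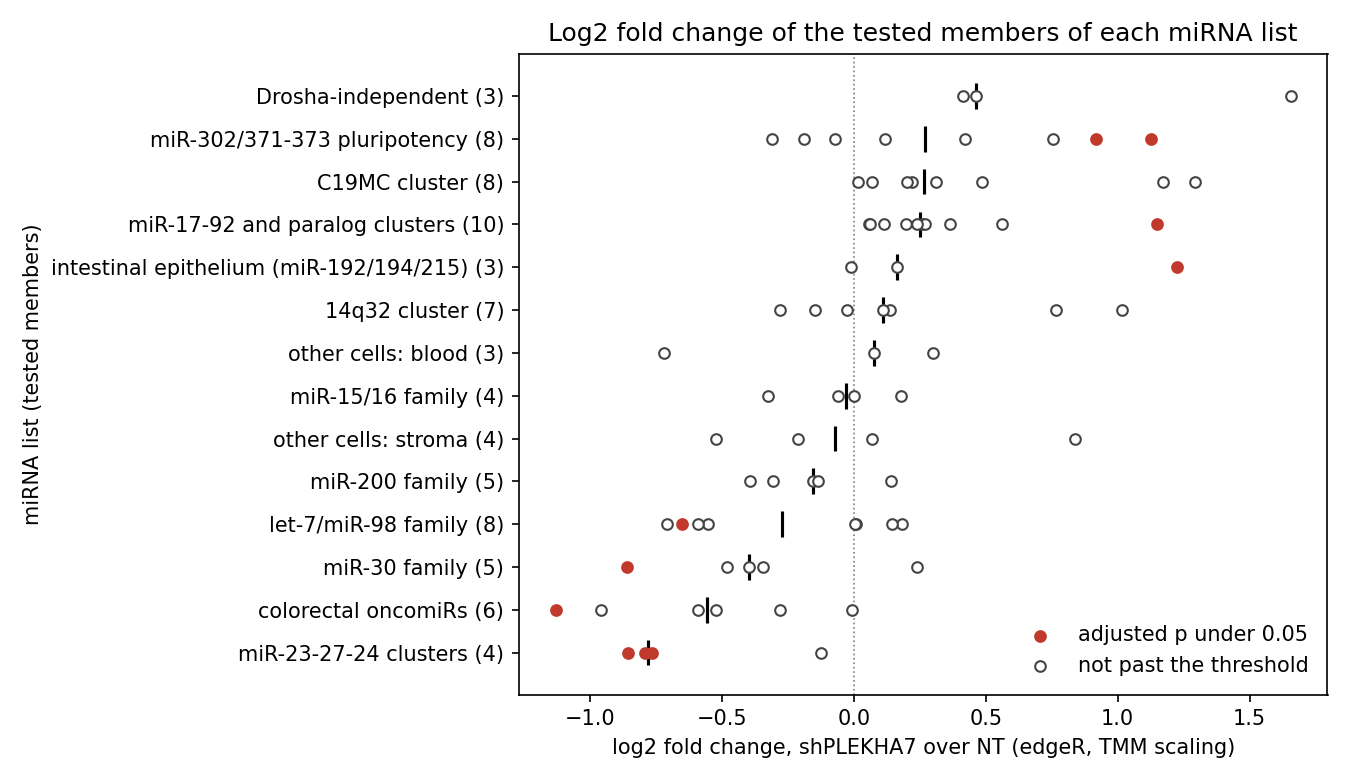
Log2 fold change (shPLEKHA7 over NT, edgeR with TMM scaling) of each tested member of the 14 tested lists, filled red where the adjusted p was under 0.05, with a bar at each list's median. The miR-23-27-24 clusters sit lowest at a median of -0.78, and the miR-17-92 clusters have all 10 members above 0, a count that is 3 under spike-in scaling.

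Whether miRNA signal as a whole shifted was asked without TMM. Under the deposited scaling the median log2 fold change of the tested probes was -0.01 (SD between replicates 0.19), and the scaled total was 44510 ± 8226 in NT and 39810 ± 7713 in shPLEKHA7 cells (2-sided exact permutation p = 0.5, the smallest possible being 0.1). Spike-in scaling moved that median to -0.29 (SD 0.14), whereas raw counts gave 0.22, so the global level was not settled by these lanes. Relative to the median of 0.06 under TMM scaling, fold changes under spike-in scaling centred on -0.27 and those under total counts on 0.15.

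The number of miRNAs above background was 181 and 148 in the NT lanes and 159, 240 and 193 in the shPLEKHA7 lanes. Group means of 165 ± 23.3 and 197 ± 40.7 came from overlapping groups (exact permutation p = 0.4). shPLEKHA7 replicate 2 had the most miRNAs detected with the lowest total count, 32138, and the lowest detection limit, 11 counts. Without it the difference of 32.8 became 11.5, and without NT replicate 3 it became 16.3. Without NT replicate 1 it was 49.3, and without shPLEKHA7 replicate 1 it was 52, with the groups apart in both cases.

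Of the 5 housekeeping mRNAs none passed limma on the deposited values, where B2M was at log2 -0.47 (SE 0.22, adjusted p = 0.422) and GAPDH at 0.21 (SE 0.25). ACTB, RPLP0 and RPL19 were at -0.06 (SE 0.26), 0.10 (SE 0.24) and 0.23 (SE 0.23). The deposited scaling sets their mean to a common value, so they give no check of RNA input. Under spike-in scaling all 5 were negative, with B2M at -0.75 (adjusted p = 0.0779).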

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

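All tests of spike-in counts below were chosen after the totals had been seen. Positive-control spike-ins, synthetic targets added to each lane in a set amount and used in none of the fixed comparisons, were counted 1.41 times as often in the shPLEKHA7 lanes (12980 ± 2000, n = 3) as in the NT lanes (9171 ± 2100, n = 2), with no overlap between groups (2-sided exact permutation p = 0.2, the smallest possible being 0.1). A lane-wide counting efficiency would leave the miRNA count per spike-in count level. That count was 4.64 ± 0.13 in the NT lanes and 3.51 ± 0.55 in the shPLEKHA7 lanes, again with no overlap (2-sided exact permutation p = 0.2). Its log2 ratio was -0.413 with a 95% interval from -0.94 to 0.12, which leaves that open. Less RNA in the shPLEKHA7 lanes, or less miRNA in the depleted cells, would lower that ratio. Neither would raise the count of spike-ins added in a set amount. Raw housekeeping counts were also higher in the shPLEKHA7 lanes (12930 ± 1532 against 10380 ± 560), while raw miRNA totals overlapped. Less RNA and less miRNA would part on the miRNA count per housekeeping count, whose log2 ratio was -0.216 with an interval from -1.03 to 0.60. With 2 NT lanes that interval does not tell them apart. Lane position is a further open explanation, since the numbers in the deposited column names put both NT lanes before the shPLEKHA7 lanes, and it was not tested.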

How the results depend on the processing

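Spike-in scaling and the fit of human probes were chosen after seeing the data. All 13 called miRNAs kept their direction in every setting that tested them, which their non-overlapping groups in the same 5 lanes made likely beforehand. All 13 stayed called under DESeq2 size factors, top-100-probe and total-count scaling, both limma fits and human probes alone (5 higher, 9 lower). The number higher was 12 under total counts, 2 by the DESeq2 Wald test, 1 with no filter, 2 among probes above background in all samples (9 of the 13 were tested there), 10 with the replicate block and 8 at an adjusted p under 0.1. The number lower was 2 under the deposited or housekeeping scaling, 23 by limma on deposited values, 29 under spike-in scaling and 13 at an adjusted p under 0.1. The deposited scaling kept 5 of the 13 (miR-19a, miR-21, miR-215, miR-503 and miR-574-5p), and DESeq2 left 123 of 204 adjusted p as NA. Leaving out each sample gave 0 to 9 higher and 0 to 11 lower, with 0 to 1 of the 13 kept when either NT sample was left out, which leaves 1 NT sample. The replicate block rests on 2 pairs with 1 residual degree of freedom, and all 13 calls were kept. Same-numbered samples correlated at 0.018 and 0.145 in their deviations, and NT replicate 1 with shPLEKHA7 replicate 2 at 0.137. The deviations of 2 NT samples mirror each other, so these correlations cannot decide whether the numbers mark pairs. Of 14 lists, 4 passed with the preset correlation, 0 with an estimated correlation, 1 by fry, 2 under the deposited scaling, 2 under spike-in scaling and 4 with the replicate block, and 2 to 4 when a sample was left out. The global shift was 0.216 on raw counts and -0.292 under spike-in scaling, and -0.104 to 0.101 when a sample was left out. The difference in detected miRNAs was 27.8 and 21.5 with the other thresholds and 11.5 to 52 when a sample was left out, and the groups no longer overlapped without NT replicate 1 (49.3) or without shPLEKHA7 replicate 1 (52). The let-7/miR-98 list passed without NT replicate 3 (adjusted p = 0.0272). The camera direction of the stroma list turned to up among probes above background in all samples (adjusted p = 0.959), with a median still at log2 -0.16. It also turned to up without shPLEKHA7 replicate 2 (adjusted p = 0.947, median -0.15), without shPLEKHA7 replicate 3 (0.898, median 0.16) and without NT replicate 1 (median 0.16). Of the 13 called, 2 moved by over 1.5 times when a sample was left out: miR-21 to -0.748 without NT replicate 3, and miR-23b to -0.475 without NT replicate 1. With all samples kept 6 others did, miR-302a, let-7g and miR-29a under spike-in scaling and miR-302d, miR-503 and miR-574-5p after background subtraction. Of 63 named miRNAs that were not called, 33 changed sign in some setting that kept all samples, none of them beyond log2 0.302 in the reported fit, and 0 of the 13 called did. Of the same 63, 18 were called in at least 1 setting that kept all samples (let-7b, let-7d, let-7i, miR-9, miR-15b, miR-19b, the joint miR-20a and miR-20b probe, miR-30b, miR-30d, miR-96, miR-126, miR-142-3p, miR-183, miR-200a, miR-205, miR-214, miR-320a and miR-372), 13 of them under spike-in scaling, 10 by limma on deposited values and 7 with the replicate block (let-7d, miR-19b, miR-30b, miR-183, miR-205, miR-214 and miR-320a). Leaving out a sample added miR-379, called without shPLEKHA7 replicate 3 (adjusted p = 0.0481). For those that changed sign, the log2 fold changes were as follows. Under DESeq2 size factors the values were let-7a -0.036, let-7f -0.032, miR-15a -0.039, miR-518f -0.021. By the DESeq2 Wald test the values were let-7a -0.036, let-7f -0.032, miR-15a -0.039, miR-518f -0.033. Under the deposited scaling, equal to the housekeeping one, the values were let-7a -0.055, let-7f -0.051, miR-15a -0.055, miR-526a+miR-518d-5p+miR-520c-5p -0.004, miR-518f -0.040. By limma on deposited values the values were let-7a -0.14, let-7f -0.14, miR-25 -0.037, miR-15a -0.15, miR-371-5p -0.007, miR-142-5p -0.076, miR-145 -0.11, miR-526a+miR-518d-5p+miR-520c-5p -0.069, miR-518f -0.12, miR-380 -0.038. After background subtraction the values were let-7f 0, miR-27a 0.30, miR-15a -0.008, miR-145 -0.018, miR-380 -0.29. With no filter the values were miR-720 -0.009, let-7a -0.16, let-7f -0.15, miR-141 -0.010, miR-25 -0.058, miR-15a -0.15, miR-371-5p -0.056, miR-142-5p -0.095, miR-145 -0.10, miR-206 -0.028, miR-526a+miR-518d-5p+miR-520c-5p -0.11, miR-518f -0.15, miR-136 -0.025, miR-380 -0.061, miR-98 -0.023. Among probes above background in all samples miR-192 was at 0.047. At a mean count of at least 100 the values were miR-200c 0.025, miR-192 0.17, miR-16 0.12, miR-371-3p 0.11, miR-203 0.008. With the replicate block the values were let-7a -0.030, miR-192 0.040, miR-29c 0.027, miR-145 -0.036, miR-380 -0.20. Under spike-in scaling the values were miR-92a -0.16, miR-720 -0.18, miR-20a+miR-20b -0.083, miR-30c -0.091, let-7a -0.34, let-7f -0.33, miR-141 -0.17, miR-25 -0.23, miR-194 -0.16, miR-15a -0.33, miR-424 -0.15, miR-371-5p -0.23, miR-223 -0.044, miR-142-5p -0.27, miR-145 -0.27, miR-206 -0.20, miR-1283 -0.13, miR-526a+miR-518d-5p+miR-520c-5p -0.27, miR-518f -0.33, miR-512-5p -0.13, miR-136 -0.19, miR-380 -0.22, let-7c -0.15, miR-98 -0.19. Scaled to the top 100 probes miR-192 was at 0.041. With total-count scaling the values were miR-192 0.078, miR-29c 0.034, miR-16 0.034, miR-222 0.039, miR-371-3p 0.021, miR-208a 0.034. Leaving out each sample in turn gave ranges of miR-720 -0.050 to 0.42, let-7a -0.053 to 0.10, let-7f -0.070 to 0.082, miR-141 -0.20 to 0.70, miR-192 -0.23 to 0.11, miR-29c -0.33 to 0.35, miR-27a -0.58 to 0.83, miR-16 -0.18 to 0.11, miR-15a -0.11 to 0.10, miR-424 -0.13 to 0.72, miR-222 -0.22 to 0.18, miR-371-5p -0.049 to 0.36, miR-142-5p -0.17 to 0.37, miR-10a -0.50 to 0.15, miR-145 -0.23 to 0.40, miR-206 -0.075 to 0.44, miR-208a -0.23 to 0.034, miR-526a+miR-518d-5p+miR-520c-5p -0.13 to 0.35, miR-518f -0.31 to 0.43, miR-655 -0.34 to 0.091, miR-136 -0.009 to 0.39, miR-429 -0.37 to 0.24. Apart from the fewer probes or samples that a filter or an omission leaves, the cause was not tested. Counts near the detection limit, 11 to 24.45 per lane, limit the dim miRNAs most.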

Other observations

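Probes now known to read fragments of tRNA formed a group that no fixed list held, and they were chosen after their values had been seen. miR-1274b was at 249 ± 24.6 normalized counts in NT and 340 ± 25.1 in shPLEKHA7 cells (log2 0.45, SE 0.14, adjusted p = 0.0976). miR-1274a, miR-1260 and miR-720 were at log2 0.36 (SE 0.20), 0.28 (SE 0.16) and 0.15 (SE 0.17), and none of the 4 was called.

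Some of the risen miRNAs lay among dim probes, which was noticed in the data. The tests of viral probes and of rises against falls were chosen after seeing it, the GC test before its result. Of the 5 risen probes 3 lay below the median abundance of 32.4 normalized counts, against 1 of the 8 that fell. The median splits the tested probes evenly, so 3 of 5 does not set the rises apart from tested probes at large. Higher nonspecific background would lift probes for viral miRNAs, which the labels give no reason to find here. The tables argue against a lane-wide form that lifts all probes alike, since the 80 viral probes gained a median of 1.53 counts (95th percentile 10.12), against at least 17.7 for each risen probe. Of the 80, 1 gained at least 17.7 counts, with a gain of 18. Background at single probes stays open: among probes with an NT mean up to 14.6, tested or not, 0 of 68 viral and 3 of 472 human ones gained as much (2-sided Fisher exact p = 1). Both limits were taken from the risen probes, and the 3 human ones are the called miR-215, miR-302d and miR-503 themselves. That comparison therefore cannot decide. The viral probe hcmv-miR-UL112, named after its values were seen, went from 14 ± 2.9 to 30.2 ± 5.7 (log2 1.10, adjusted p = 0.0602), and 9 ± 2.83 viral probes were detected per NT lane against 14.3 ± 5.13 per shPLEKHA7 lane (exact permutation p = 0.4). The tables argue against GC content of the target, since removing its trend over all tested probes took the median rise from log2 1.15 to 1.19, a fall of -3.4%. Chance spread of dim probes stays open: rises of at least log2 0.92 outnumbered falls 12 to 2 in the fit, a ratio of 6. On plain means of log2 counts the real split gave 13 rises to 1 fall, against a ratio of at most 3 in any other. Setting shPLEKHA7 replicates 1 and 2 apart gave 1 rise to 9 falls. But 10 splits are too few to set this against chance, and the filter on 2 samples is more easily met by 3 shPLEKHA7 samples than by 2 NT samples.

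A hypothesis that miRNAs of 1 genomic cluster changed alike, tested after many of the fold changes had been seen, was left unsettled. Among 152 of 204 tested probes whose loci lie in 1 cluster (neighbouring genes within 10000 bases), 75 clustered pairs of unlike sequence differed by a mean of log2 0.54, against 0.58 in random pairs (1-sided permutation p = 0.3349). Over all 91 clustered pairs the mean was 0.51, and it was 0.42 without the cluster of miR-503. Leaving out any other cluster gave 0.49 to 0.56, and no permutation was run for these omissions. Cross-hybridisation between like sequences was not resolved either, with 41 like pairs from different clusters differing by 0.50 (1-sided permutation p = 0.2157).

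Of the 10 splits of the 5 samples into 2 and 3, 1 gave as many called probes as the real one, the real one itself, with 13 calls against at most 1 in any other. The 10 splits are too few for a share under 0.05.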
